A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

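RNA of the strain CEN.PK113-7D was measured on 17 Affymetrix Yeast Genome S98 arrays, 4 from steady-state cultures and 13 from cultures in the temperature cycle. Per the labels' protocols, 200 ng of total RNA was amplified with a kit that primes at the 3' end. The deposited values are probe set intensity on a linear scale with 1 decimal, which the authors made before deposit. Per the labels, RMA was the processing tool, with no version or further steps stated. The values themselves show another pattern, since they reach 0 and every array has the same mean of about 240.2 once the top and bottom 2% of its probe sets are left out, which is a scaling per array to a common target. How the authors reached these values therefore stays unknown, and they were used as deposited. No scan dates, detection calls or genome build come with them, so no batches by date could be examined and no coordinates are given.

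From here on the steps are those of the re-analysis. Values under 1 were set to 1 and log2 was taken. Of the 9335 probe sets, 6504 had a single gene in the platform annotation, 328 had several, 2443 had none there and 60 were controls. Gene names were updated by gene identifier to the R64 reference (all 6504 matched), which was used only for names, gene types and gene lengths. Of several probe sets of a gene, the one with the highest mean stood for it, which left 5656 genes, 5486 protein coding and 170 other RNA genes. For 315 genes with several probe sets, none had sets called in opposite directions between the cold and warm point of the cycle. Background was the 95th percentile of 28 control probe sets without a target in the labelled RNA (log2 3.387, signal 10.46), and 5368 genes lay above it on average. Where both arrays of a group lay under background, the change is given as "at least" the bright group's mean over the background, and no fold is given where both groups lay under it.

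The series asked how far responses to the cycle follow from steady states, and labels gave the groups SS_12, SS_30, DTC_30, DTC_21_decreasing, DTC_14.6, DTC_12, DTC_21_increasing and DTC_27.4. Hours in the cycle were computed from the sine formula in the labels, which matched the stated temperatures within 0.0411 °C. The main model was limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 1 mean per group over 16 arrays, a shared spread with 8 residual degrees of freedom, and empirical Bayes moderation. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Pairwise contrasts, the difference of both temperature effects, a moderated F test over the 6 cycle points and a 24-h cosine and sine model on the 12 cycle arrays were tested, all two-sided. Steady-state replicates came from independent cultures. The cycle arrays all came from the same 2 cultures, sampled over cycles 5 and 6, and the labels do not tie a sample to a culture, so the p-values treat arrays as independent although cycle points share cultures. The number of arrays limits the precision. In simulated data, 200 of 5656 genes were changed at DTC_12 and 200 others were given a rhythm over the cycle. The comparison DTC_12 versus DTC_30 recovered 2.99% of genes changed by 0.5 on the log2 scale, 41.8% of those changed by 1 and 92.4% of those changed by 2. For the harmonic, 89% of genes with an amplitude of 1 were called, with a median error of the peak of 0.309 h. In each test 11 unchanged genes were called. The simulated noise was independent between genes and arrays, unlike arrays that share cultures, so these rates need not hold for the real comparisons.

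Gene lists, 40 in all, were fixed before the data were examined, as were the comparisons, the main model, the alternatives named as planned and the rule for named genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rule named, for each pairwise comparison, up to 8 rises and 8 falls of the largest size past the test without overlap between the groups' arrays, up to 2 risen and 2 fallen members of each list past camera, the 4 genes of largest amplitude per 6-h window of the peak, and 26 index genes. PAU genes and other near-identical copies are read as uncertain. The text gives a selection of the genes under this rule.

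An array numbered 3 at 27.4 °C was left out, since the series describes an extra analytical duplicate at this point. The labels do not say which of the 3 arrays is the duplicate or which culture it came from, so the 2 arrays kept may come from 1 culture. The array numbered 3 correlated more closely with each of them (0.9759 and 0.9712) than they did with each other (0.9617). Alternatives were another normalization (quantile, array medians), a floor of 12, removal of dim genes, all probe sets, an intensity trend with robust prior, only the groups compared in the fit, array weights, a 2-fold limit, an adjusted p under 0.01, other treatments of the array numbered 3, the replicate number in the model, a 12-h harmonic, the fry test and leaving out each replicate. A length correction, leaving out 3 arrays that stood apart from their replicate, a crossed numbering and leaving out the point at 21 °C rising were added after the data were seen. Which array of such a pair deviated cannot be told from the pair, so the choice of these 3 was arbitrary in that respect.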

Results

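The series followed messenger RNA in anaerobic, glucose-limited chemostats of the budding yeast strain CEN.PK113-7D, a MATa haploid that carries the SUC2 invertase gene. A chemostat is a continuous culture with an inflow of fresh medium, here at a dilution rate of 0.03 per h. At steady state this inflow sets the growth rate, while at single points of a temperature cycle the momentary growth rate need not equal it. Some cultures were held at a constant 12 °C (SS_12) or 30 °C (SS_30) until steady state. Others went through daily temperature cycles (DTC) in which the temperature followed a sine wave of 24 h between 30 and 12 °C, and were sampled in the fifth and sixth cycle. The cycle was sampled at 30 °C (hour 0), at 21 °C while the temperature fell (hour 6), at 14.6 °C (hour 9), at 12 °C (hour 12), at 21 °C while it rose (hour 18) and at 27.4 °C (hour 21).

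Each of the 8 groups had 2 arrays in the comparisons, and an array numbered 3 at 27.4 °C was kept out of them. Expression was measured as probe set signal on Affymetrix Yeast Genome S98 arrays, scaled per array before deposit and turned to log2 here, for 5656 genes. Between 5305 and 5395 of these lay above background on each array used. Replicate arrays correlated at 0.956 to 0.984 across genes. The number of arrays, not a read depth, limits the precision. All changes below are log2 differences with their standard error (SE) from a limma model with 2 arrays per group, and the genes listed as largest changes had no overlap between the arrays of the groups compared.

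The steady-state comparison asked what a constant low temperature does at an unchanged growth rate. At 12 °C the hexose transporter gene HXT4 was 29.7-fold higher than at 30 °C (log2 change 4.89 ± 0.39 SE, adjusted p = 7.94e-06). PDR12, which encodes an exporter of weak organic acids, was 18.2-fold higher (4.19 ± 0.29, adjusted p = 2.94e-06), and the methyltransferase gene EFM6 was higher too (4.24 ± 0.32, adjusted p = 6.26e-06). Transporter genes and a stress gene stood among the deepest falls. DIP5, a permease for acidic amino acids, fell (-6.86 ± 0.46, adjusted p = 2.94e-06). So did the hexose transporter gene HXT5 (-5.98 ± 0.33, adjusted p = 5.07e-07) and the stress gene GRE1 (-5.78 ± 0.27, adjusted p = 1.83e-07). The mean of the dimmer group lay under background for DIP5, HXT5 and EFM6, so their sizes are uncertain. With the floor of 12 they were -6.53, -5.61 and 3.69. The uridine permease gene FUI1 was at least 13.6-fold lower and HMS2 at least 9.25-fold lower, since both were under background at 12 °C. PRM3, a gene for nuclear fusion in mating, was at least 10.25-fold higher. Of the 16 largest changes, 7 belonged to probe sets of transfer RNA genes, such as YNCM0020W (at least 5.21-fold higher) and YNCP0009W (at least 14.7-fold lower). With the floor of 12 their log2 changes were 2.18 and -3.68. Such genes have near-identical copies, and whether the priming at the 3' end labelled transfer RNA is not known. Which RNA these probe sets read is therefore uncertain.

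Of 29 heat shock and chaperone genes measured, 13 fell and none rose in the constant cold (15 lower and 1 higher adjusted over the list alone), with HSP30 at -4.27 (adjusted p = 2.94e-06), HSP26 at -3.83 (adjusted p = 8.88e-07) and the disaggregase HSP104 at -0.99 (adjusted p = 0.0199). HSP104 no longer passed in 4 of 19 alternatives. The list test, limma's camera, gave adjusted p = 2.15e-07, but adjusted p = 0.114 with an estimated correlation. Of 30 targets of the stress regulators Msn2 and Msn4, 16 fell and 2 rose (18 and 3 adjusted over the list alone; camera adjusted p = 1.9e-05, but adjusted p = 0.114 with an estimated correlation). The risers YGP1 (0.91) and HOR7 (0.85) no longer passed after quantile normalization (0.62 and 0.40), while FMP45 fell by 4.59. Genes of gluconeogenesis and the glyoxylate cycle gave 8 falls and 1 rise among 24 (8 and 1 adjusted over the list alone), with PCK1 at -2.98 and its activator CAT8 at -2.66 (camera adjusted p = 0.00817, but adjusted p = 0.437 with an estimated correlation).

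Among 80 ribosomal protein genes 30 rose and none fell in the constant cold (38 rose adjusted over the list alone), led by RPS22B (1.61) and RPS26B (1.21), with a median log2 change of 0.63 (camera adjusted p = 4.96e-11, but adjusted p = 0.342 with an estimated correlation). RPS26B no longer passed in 3 of 19 alternatives. Of 95 ribosome biogenesis genes 26 rose and 1 fell (30 and 1 adjusted over the list alone). SAS10 (2.26) and the RNA helicase gene DBP2 (1.61) rose, and ESF1 fell by 2.57 (camera adjusted p = 2.15e-07, but adjusted p = 0.114 with an estimated correlation). Ergosterol synthesis showed 6 rises among 25 genes (6 adjusted over the list alone), with ERG28 at 0.92 and ERG2 at 0.90, which did not pass after quantile normalization (0.62 and 0.42). Its camera adjusted p of 0.00101 became 0.119 after quantile normalization and adjusted p = 0.114 with an estimated correlation.

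The iron and copper genes were split at steady state. Of 22 measured, 9 fell and 2 rose (10 and 2 adjusted over the list alone). The iron oxidase and permease genes FET3 (-3.67, adjusted p = 7.44e-06, and -3.11 with the floor of 12, its mean at 12 °C being under background) and FTR1 (-2.68, adjusted p = 1.72e-05) fell. The copper transporter gene CTR1 rose by 1.43 (adjusted p = 0.00183) and FRE2 by 1.25 (adjusted p = 0.00959), though FRE2 no longer passed in 3 of 19 alternatives. The list as a whole had camera adjusted p = 0.0286, which became 0.0583 after quantile normalization and adjusted p = 0.342 with an estimated correlation. Of 10 seripauperin (PAU) genes, cell wall mannoprotein genes too alike for the probes to be certain which member is read, 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00101, but adjusted p = 0.437 with an estimated correlation), such as PAU23 (-2.02) and PAU19 (-1.63). Of the storage carbohydrate genes tested singly, the glycogen genes GPH1 (1.44, adjusted p = 0.0154) and GSY2 (1.08, adjusted p = 0.0195) rose, though neither passed without SS_30 replicate 2 (0.98 and 0.69). The trehalose genes TPS1 (adjusted p = 0.876) and TSL1 (adjusted p = 0.633) did not pass. The pheromone gene MF(ALPHA)1, normally silent in MATa cells, rose by 3.51 ± 0.24 (adjusted p = 2.94e-06), from a log2 signal of 7.86 ± 0.38 (SD, n = 2) to 11.36 ± 0.01 (SD, n = 2), and MF(ALPHA)2 was at least 2.56-fold higher, being under background at 30 °C. The signal of MF(ALPHA)1 at 30 °C already lay over the background of log2 3.387.

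In all, 1256 of 5656 genes differed between the steady states, 564 higher and 692 lower at 12 °C, of which 342 and 523 changed at least 2-fold. Centring each array on its median moved every log2 change by 0.12 and quantile normalization changed it by a median of 0.113 over genes, and the centred split was 730 higher and 567 lower. The count fell to 685 with only the 4 arrays compared in the fit, to 565 without SS_12 replicate 1, to 602 without SS_30 replicate 1 and to 671 without SS_30 replicate 2.

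The comparison of the coldest with the warmest point of the cycle asked what the daily drop in temperature does. Ribosome biogenesis was higher and respiration, stress and alternative carbon genes were lower at the cold point. The RNA helicase gene DBP2 was 26.8-fold higher at 12 °C (log2 change 4.75 ± 0.20 SE, adjusted p = 7.11e-08), and CLB1, which encodes a mitotic cyclin, was 14.5-fold higher (3.86 ± 0.30, adjusted p = 8.26e-06). HXT4 (3.68 ± 0.39, adjusted p = 4.01e-05) and EFM6 (4.01 ± 0.32, adjusted p = 9e-06) rose here as well, and the transporter gene AZR1 was at least 20.05-fold higher. Among the deepest falls were those of the hydrophilin gene SIP18 (-5.33 ± 0.20, adjusted p = 3.66e-08), the gluconeogenic PCK1 (-5.30 ± 0.39, adjusted p = 5.87e-06), the small heat shock protein gene HSP26 (-5.07 ± 0.23, adjusted p = 7.11e-08) and YRO2 (-5.39 ± 0.50, adjusted p = 1.81e-05). YKL107W, under background at 12 °C, was at least 3.885-fold lower. ISF1 (-4.97), RGI2 (-4.82) and COX26 (-4.48), linked to respiratory growth, also fell.

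Respiratory genes moved almost as a block in these anaerobic cultures. Of 37 respiratory chain genes 36 fell (37 adjusted over the list alone), with a median of -2.05, SDH3 at -3.14 and the cytochrome c gene CYC1 at -3.07 (camera adjusted p = 1.78e-22, and adjusted p = 0.00709 with an estimated correlation). The tricarboxylic acid cycle gave 12 falls among 16 genes (12 adjusted over the list alone), including SDH1 (-2.84) and MDH1 (-2.79), and 57 of 71 mitochondrial ribosomal protein genes fell (63 adjusted over the list alone), including MRPL4 (-2.28). Their camera adjusted p-values were 3.57e-08 and 7.76e-18, with 0.00709 and 0.0291 under an estimated correlation. Gluconeogenesis and glyoxylate genes fell in 17 of 24 cases (18 adjusted over the list alone), and CAT8 was at least 10.3-fold lower. Peroxisomal beta-oxidation genes fell in 12 of 18 (14 adjusted over the list alone), FOX2 by 2.46. The maltose and sucrose genes fell in 7 of 8 (7 adjusted over the list alone), with MAL11 at -3.82 and the invertase gene SUC2 at -3.75 ± 0.22 (adjusted p = 6.47e-07). The camera adjusted p-values of these 3 lists were 4.82e-09, 9.65e-07 and 1.15e-06, with adjusted p = 0.0372, 0.0291 and 0.0471 under an estimated correlation.

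Stress genes were lower at the cold point. Of the 30 Msn2 and Msn4 targets 24 fell and none rose (26 fell adjusted over the list alone; camera adjusted p = 2.27e-11, and adjusted p = 0.00709 with an estimated correlation). Among 29 heat shock and chaperone genes 19 fell and 3 rose (21 and 3 adjusted over the list alone; camera adjusted p = 2.13e-08, and adjusted p = 0.0324 with an estimated correlation). HSP12, a stress target, fell by 0.95 (adjusted p = 0.00935, but -0.59 and adjusted p = 0.106 with the length correction) and HSP30 by 4.37, while CCT2 (1.20) and TCP1 (0.95), subunits of the cytosolic chaperonin, rose. Glycogen genes fell in 10 of 13 cases (10 adjusted over the list alone), GIP2 by 2.33 and GLC3 by 2.11 (camera adjusted p = 3.08e-05, but adjusted p = 0.108 with an estimated correlation). TSL1, a subunit gene of trehalose synthase, fell by 1.95 (adjusted p = 0.000307).

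Genes of ribosome production and lipid synthesis were higher at the cold point. Of 95 ribosome biogenesis genes 82 rose and none fell (87 rose adjusted over the list alone), with a median of 1.52 and the nucleolar gene NSR1 at 2.97 ± 0.27 (adjusted p = 1.63e-05; camera adjusted p = 6.12e-25, and adjusted p = 0.00346 with an estimated correlation). RNA polymerase I and III genes rose in 16 of 23 cases (18 adjusted over the list alone), RRN3 by 1.95 and RPA49 by 1.86, and translation factor genes in 13 of 31 (15 adjusted over the list alone), DED1 by 2.35. Their camera adjusted p-values were 2.76e-06 and 2.69e-05, and adjusted p = 0.00709 and 0.011 with an estimated correlation. Ergosterol genes rose in 13 of 25 cases (16 adjusted over the list alone), CYB5 by 1.86 and ERG20 by 1.54 (0.99 without DTC_30 replicate 1). Phospholipid genes rose in 13 of 23 and fell in 1 (13 and 1 adjusted over the list alone), INO1, the first enzyme of inositol synthesis, by 3.56 and its activator INO2 by 2.91. Zinc-responsive genes rose in 7 of 10 (7 adjusted over the list alone), among them IZH2 and the zinc transporter gene ZRT1 (1.42). The camera adjusted p-values of these 3 lists were 3.8e-05, 4.4e-05 and 0.000983, with adjusted p = 0.0291, 0.00953 and 0.0291 under an estimated correlation. Genes of the transition from G1 to S phase rose in 24 of 50 cases and fell in 1 (26 and 1 adjusted over the list alone), with RNR1 at 1.85 and MCD1 at least 2.71-fold higher (camera adjusted p = 2.69e-05, but adjusted p = 0.0652 with an estimated correlation). Cell wall genes rose in 11 of 28 and fell in 1 (12 and 1 adjusted over the list alone), CWP1 by 2.94, whereas SPI1 fell by 2.71 (camera adjusted p = 0.00219, but adjusted p = 0.235 with an estimated correlation).

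In all, 1855 genes differed between the cold and the warm point, 931 higher and 924 lower, of which 646 and 706 changed at least 2-fold. Across 4257 genes the change correlated with gene length at Spearman's rho = 0.172, with genes not independent replicates. The count was 782 with only the 4 arrays compared in the fit and 1225 without DTC_12 replicate 2.

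**Figure D1:**
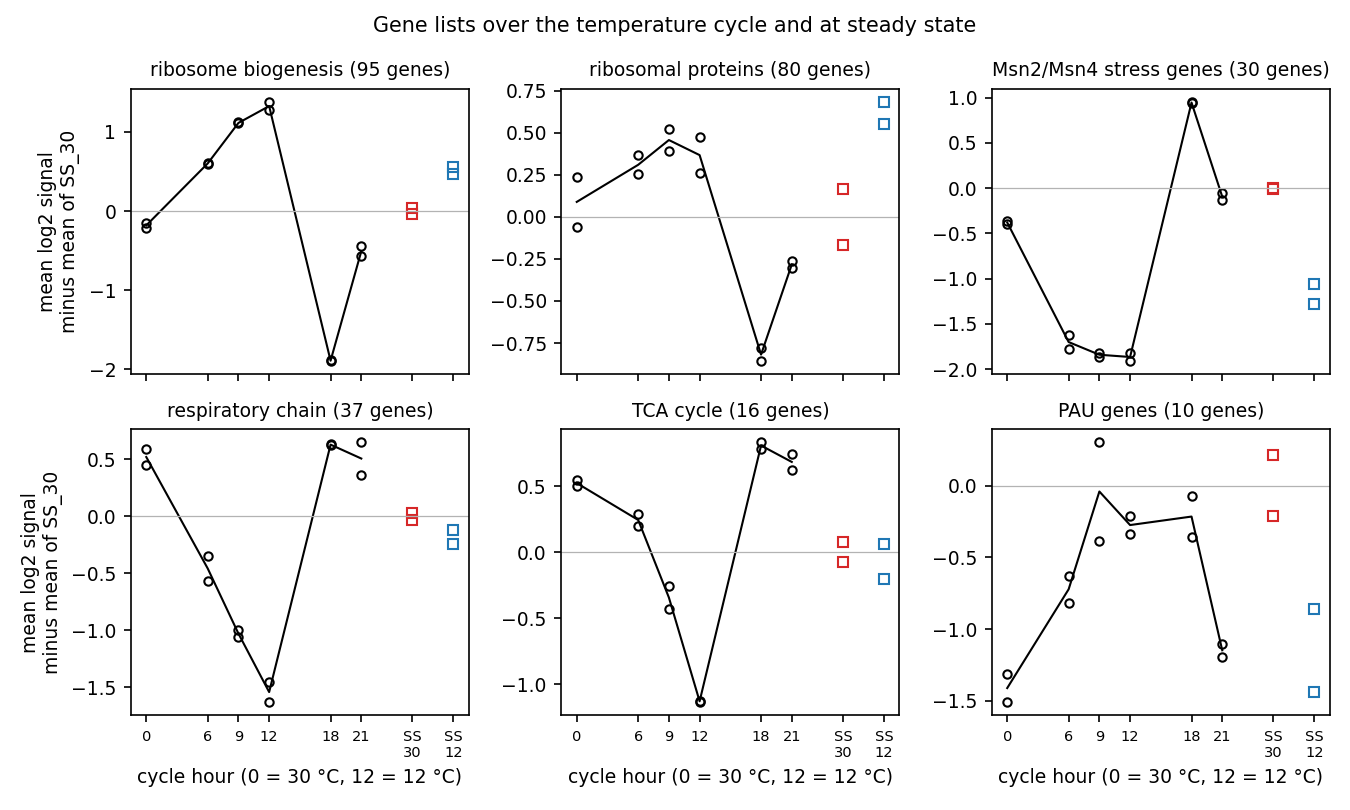
Mean log2 signal of 6 gene lists, minus their mean at SS_30, against the hour of the cycle (circles and line: the 2 DTC arrays per point and their mean) with the steady states at the right (squares: single arrays, red for 30 °C and blue for 12 °C). Ribosome biogenesis genes ran from 1.33 at hour 12 to -1.89 at hour 18, while respiratory chain genes ran from -1.54 to 0.63 and Msn2 and Msn4 targets from -1.87 to 0.95 between the same hours.

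How far the cycle can be predicted from steady state was asked by setting both temperature effects side by side. Some genes that fell at the cold point of the cycle did not fall between steady states. SUC2 fell by 3.75 in the cycle and changed by 0.05 between steady states (difference -3.80 ± 0.30 SE, adjusted p = 4.86e-05). The copper transporter genes CTR3 and CTR1 reversed, while CTR2 passed in neither setting. CTR3 rose by 2.42 between steady states and fell by 3.14 in the cycle (difference -5.56 ± 0.40, adjusted p = 3e-05), and CTR1 rose by 1.43 and fell by 2.55 (difference -3.98 ± 0.34, adjusted p = 8.5e-05). HXT5 fell in both, less deeply in the cycle (log2 difference 3.98 ± 0.47, adjusted p = 0.000782, and 3.61 with the floor of 12, its mean at SS_12 being under background).

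Across the 5656 genes the effects correlated at Pearson's r = 0.471 and Spearman's rho = 0.426, with genes not independent replicates and no array shared between the effects. In both settings 254 genes were higher in the cold, against 92.84 for independent lists of these sizes, and 290 were lower, against 113. Another 61 genes were called in opposite directions, fewer than were shared in either direction, and no number for independent lists was computed for them. Of the 2506 genes called in either setting, 74.1% had effects of the same sign, and 699 of them (27.9%) differed between the settings when the difference itself was tested. Over all 5656 genes this share was 12.9%. The same arrays gave the calls and the difference, so choosing called genes can raise the share. Genes that did not pass are not shown to have equal effects.

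Several lists of respiration and carbon metabolism had lower effects in the cycle. Of 37 respiratory chain genes 30 had a lower effect in the cycle and none a higher one (35 lower adjusted over the list alone), with SDH3 at -3.35 and NDI1 at -3.01 (camera adjusted p = 2.32e-24, and adjusted p = 0.0131 with an estimated correlation). The same held for 8 of 16 tricarboxylic acid cycle genes (13 adjusted over the list alone; MDH1 at -2.79), 33 of 71 mitochondrial ribosomal protein genes (57 adjusted over the list alone; MRPL24 at -2.37) and 7 of 8 maltose and sucrose genes (8 adjusted over the list alone). Their camera adjusted p-values were 4.12e-09, 8.62e-22 and 2.73e-08, with adjusted p = 0.0131, 0.0313 and 0.0496 under an estimated correlation. Glycogen genes had lower effects in 6 of 13 cases (7 adjusted over the list alone), with GPH1 at -2.14 and GSY2 at -1.95 (camera adjusted p = 8.2e-06, but adjusted p = 0.1 with an estimated correlation).

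Higher effects in the cycle stood out for ribosome production. Among 95 ribosome biogenesis genes 20 had a higher effect and none a lower one (36 higher adjusted over the list alone), with ESF1 at 3.37, DBP2 at 3.14 and NSR1 at 1.65 (camera adjusted p = 1.76e-12, and adjusted p = 0.0135 with an estimated correlation). All 10 PAU genes had a higher effect (10 adjusted over the list alone), PAU15 by 3.04 and PAU19 by 2.70, though the probes may read several of these near-identical genes (camera adjusted p = 1.68e-08, but adjusted p = 0.1 with an estimated correlation). Phospholipid genes were higher in 5 of 23 cases and lower in 1 (7 and 2 adjusted over the list alone), with INO2 at 4.73 ± 0.71 (camera adjusted p = 0.000817, and adjusted p = 0.0313 with an estimated correlation). The phosphate transporter gene PHO84 (4.11) was among 4 of 15 phosphate genes with a higher effect (4 adjusted over the list alone; camera adjusted p = 0.0122, but adjusted p = 0.102 with an estimated correlation). Ribosomal protein genes had a camera adjusted p of 0.00069 for a lower effect, with 1 of 80 called, and this direction turned after quantile normalization (adjusted p = 0.532) and gave adjusted p = 0.432 with an estimated correlation.

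In all, the effects of 729 genes differed, 371 higher and 358 lower in the cycle. Centring on array medians moved the difference by -0.169 and quantile normalization by a median of -0.116 over genes, and the centred split was 268 higher and 476 lower. The count was 343 with only the 8 arrays compared in the fit, 472 without SS_12 replicate 1, 421 without SS_30 replicate 1, 410 without SS_30 replicate 2 and 429 without DTC_12 replicate 2, and the difference correlated with gene length at Spearman's rho = 0.229 across 4257 genes.

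**Figure D2:**
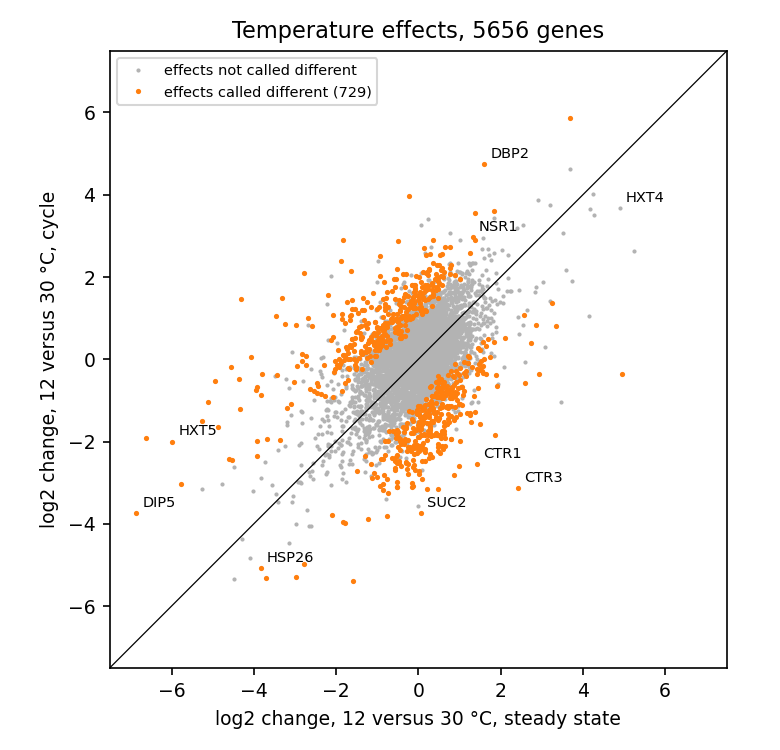
Log2 change from 30 to 12 °C between steady states (horizontal) against the log2 change between the warmest and coldest points of the cycle (vertical) for 5656 genes, with the line of equal effects. Orange points are the 729 genes whose effects differed, CTR3 and SUC2 below the line and DBP2 and HXT5 above it.

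Cycling and constant cultures were also compared at the same temperature, which asks whether a culture in the cycle matches the steady state it passes through. At 30 °C few single genes differed. The ethanol O-acyltransferase gene EEB1 was 4.18-fold higher in the cycle (log2 change 2.06 ± 0.29 SE, adjusted p = 0.00531), the maltose permease gene MPH2 was 3.86-fold higher (1.95 ± 0.25, adjusted p = 0.00366), and the flocculin gene FLO11 (1.75 ± 0.33, adjusted p = 0.0276) and ACH1 (1.77 ± 0.36, adjusted p = 0.0408) rose too. GRE1 fell by 3.18 ± 0.27 (adjusted p = 0.000165), while YDL218W (-2.88 ± 0.30, adjusted p = 0.00115) and HXT5 (-2.73 ± 0.33, adjusted p = 0.00336) fell too. The iron permease gene FTR1 fell by 1.71 (adjusted p = 0.00518) and CTR1 rose by 1.13 (adjusted p = 0.0478).

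Some lists moved together at 30 °C although few members passed on their own. No respiratory chain gene of 37 passed over all genes, 9 were higher adjusted over the list alone, and the median was 0.54 (camera adjusted p = 2.08e-13, but adjusted p = 0.0852 with an estimated correlation). The tricarboxylic acid cycle list had a median of 0.50, with 3 of 16 genes higher adjusted over the list alone (camera adjusted p = 1.23e-06, and adjusted p = 0.0432 with an estimated correlation). Of the maltose and sucrose genes 1 of 8 rose (7 adjusted over the list alone), and of the PAU genes 5 of 10 fell (10 adjusted over the list alone), such as PAU17 (-1.74). Their camera adjusted p-values were 1.79e-06 and 7.55e-13, but both had adjusted p = 0.092 with an estimated correlation. Gluconeogenesis genes rose in 2 of 24 cases (3 adjusted over the list alone), FBP1 by 1.45 and AGX1 by 1.26 (camera adjusted p = 4.47e-05, but adjusted p = 0.148 with an estimated correlation). Of the genes named at 30 °C, ACH1 no longer passed in 11 of 19 alternatives, CTR1 in 10, FLO11 in 8, FBP1 and AGX1 in 7 and PAU17 in 6. At 30 °C 68 genes differed, 19 higher and 49 lower in the cycle, and 651 had an unadjusted p under 0.05. Centring on array medians gave 23 higher and 31 lower, and limma called 0 genes with only the 4 arrays compared in the fit (448 at an unadjusted p under 0.05), 106 with an intensity trend and robust prior, 17 with array weights, 111 with a length correction, 27 without the 3 arrays that stood apart from their replicate, 15 without SS_30 replicate 1, 17 without SS_30 replicate 2 and 29 without DTC_30 replicate 1.

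At 12 °C the cycle and the steady state lay further apart. The polyamine exporter gene TPO2 was 15.5-fold higher in the cycle (log2 change 3.96 ± 0.27 SE, adjusted p = 8.45e-06), and the mannosyltransferase gene KTR2 rose (3.75 ± 0.57, adjusted p = 0.0017, and 2.59 with the floor of 12). OPT2 (3.64 ± 0.55, adjusted p = 0.00171) and the amino acid permease gene DIP5 (3.05 ± 0.46, adjusted p = 0.00162, and 2.72 with the floor of 12) rose too. HMS2 was at least 5.54-fold higher. CTR3 fell by 4.20 ± 0.28 (adjusted p = 8.45e-06), SUC2 by 3.21 ± 0.22 (adjusted p = 8.45e-06), AIM33 by 3.13 ± 0.31 (adjusted p = 0.000173, and -2.66 with the floor of 12) and the stress gene DDR2 by 2.92 ± 0.22 (adjusted p = 1.49e-05).

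Respiratory chain genes were lower at the cold point of the cycle than in the constant cold in 33 of 37 cases (35 adjusted over the list alone), with SDH3 at -2.38 and COX7 at -2.30 (camera adjusted p = 2.02e-20, and adjusted p = 0.016 with an estimated correlation). Of the 95 ribosome biogenesis genes 42 were higher and none lower (54 higher adjusted over the list alone), UTP6 by 2.06 (camera adjusted p = 2.73e-15, and adjusted p = 0.016 with an estimated correlation). Stress targets fell in 15 of 30 cases and rose in 1, XBP1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.07e-06, and adjusted p = 0.0397 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 38 of 71 cases (49 adjusted over the list alone), MRP8 by 2.23 (camera adjusted p = 2.56e-15, and adjusted p = 0.0449 with an estimated correlation). Glycogen genes fell in 9 of 13 (9 adjusted over the list alone), GPH1 by 2.10 (camera adjusted p = 5.42e-06, but adjusted p = 0.0865 with an estimated correlation), and glycolysis and fermentation genes in 6 of 23 with 1 rise (7 and 1 adjusted over the list alone), ADH5 by 2.32 and HXK2 by 1.70. The camera adjusted p of the glycolysis list was 0.000176, but 0.0588 after quantile normalization and adjusted p = 0.0696 with an estimated correlation.

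At 12 °C 1029 genes differed, 500 higher and 529 lower in the cycle, and the change correlated with gene length at Spearman's rho = 0.264 across 4257 genes. The count was 0 with only the 4 arrays compared in the limma fit (1568 at an unadjusted p under 0.05), 582 without the 3 arrays that stood apart from their replicate, 481 without SS_12 replicate 1, 676 without DTC_12 replicate 1 and 365 without DTC_12 replicate 2.

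The cycle passed 21 °C in both directions, and comparing the falling with the rising side asked how much the same momentary temperature leaves undetermined. Ribosome biogenesis genes were higher and Msn2 and Msn4 targets were lower while the temperature fell. The GTPase gene RBG1 was at least 49.8-fold higher on the falling side, INO2 at least 12.05-fold higher and PUF6, a factor of ribosome assembly, at least 9.07-fold higher, since all 3 were under background on the rising side. SOL4 (-5.05 ± 0.29 SE, adjusted p = 4.97e-07), the transketolase gene TKL2 (-4.85 ± 0.42, adjusted p = 6.11e-06), the aldehyde dehydrogenase gene ALD3 (-4.67 ± 0.31, adjusted p = 1.68e-06) and RTN2 (-4.59 ± 0.20, adjusted p = 1.21e-07) fell.

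Of the 95 ribosome biogenesis genes 93 were higher on the falling side and none lower (95 higher adjusted over the list alone), with a median of 2.47, ARX1 at 4.53 (adjusted p = 4.97e-07) and DBP3 at 4.33 (adjusted p = 4.69e-06). The list had camera adjusted p = 1.3e-39, and adjusted p = 0.000636 with an estimated correlation. RNA polymerase I and III genes rose in 20 of 23 cases (20 adjusted over the list alone), RPA43 by 4.22 (3.88 with the floor of 12), and translation factor genes in 21 of 31 (25 higher and 1 lower adjusted over the list alone), TIF3 by 1.87. Their camera adjusted p-values were 6.89e-12 and 6.88e-07, and adjusted p = 0.000916 and 0.00582 with an estimated correlation. Among 80 ribosomal protein genes 68 rose (73 adjusted over the list alone), RPL7B by 3.54 (camera adjusted p = 1.53e-16, but adjusted p = 0.165 with an estimated correlation).

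Of the 30 Msn2 and Msn4 targets 27 fell and none rose on the falling side (27 adjusted over the list alone), with a median of -2.87 (camera adjusted p = 1.48e-21, and adjusted p = 0.000993 with an estimated correlation). Oxidative stress genes fell in 16 of 29 cases and rose in 2 (19 and 2 adjusted over the list alone), SOD2 by 3.31 and TSA2 by 3.27 (camera adjusted p = 3.33e-07, and adjusted p = 0.00292 with an estimated correlation). Trehalose genes fell in 8 of 10 cases and rose in 1 (8 and 1 adjusted over the list alone), TSL1 by 3.54 (adjusted p = 3.83e-06) and TPS1 by 2.35 (adjusted p = 7.47e-06), and glycogen genes fell in 10 of 13 (11 adjusted over the list alone), GSY2 by 3.20 (adjusted p = 6.95e-06). These lists had camera adjusted p = 0.000311 and 3.18e-07, but adjusted p = 0.172 and 0.1 with an estimated correlation. Heat shock genes fell in 16 of 29 cases and rose in 1 (18 and 1 adjusted over the list alone), HSP26 by 4.02 and HSP30 by 3.55 (camera adjusted p = 3.18e-07, but adjusted p = 0.073 with an estimated correlation). The chaperone gene SSA4 fell by 2.76 (adjusted p = 6.95e-06) and the glycerol synthesis gene GPD1 by 1.56 (adjusted p = 0.000665), while the hexose transporter gene HXT2 rose by 2.34 (adjusted p = 1.14e-05). In all, 1915 genes differed at 21 °C, 1055 higher and 860 lower on the falling side, of which 780 and 635 changed at least 2-fold. Centring on array medians moved the change by -0.118 and quantile normalization by a median of -0.111 over genes.

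Over the whole cycle, genes were sorted by when they peaked and by whether they followed the temperature itself. YRO2 and SIP18 peaked late in the cycle, with fitted amplitudes of 3.17 (peak at hour 21.3, adjusted p = 1.38e-05) and 2.95 (hour 21.5, adjusted p = 1.98e-05). PCK1 peaked with the warmth (amplitude 2.77, hour 0.109, adjusted p = 6.37e-05), DBP2 at hour 10.2 (amplitude 2.50, adjusted p = 1.38e-05) and ALD3 at hour 16.9 (amplitude 1.99, adjusted p = 0.0159). HSP26 ran from a log2 signal of 5.94 ± 0.26 (SD, n = 2) at 12 °C to 11.83 ± 0.10 (SD, n = 2) at 21 °C rising. NSR1 went the other way, from 10.73 ± 0.01 (SD, n = 2) to 6.25 ± 0.14 (SD, n = 2) at the same points. TPS1 stood at 9.12 ± 0.27 (SD, n = 2) at 21 °C falling and at 11.47 ± 0.03 (SD, n = 2) at 21 °C rising, and HXT2 was highest at 14.6 °C with 10.69 ± 0.26 (SD, n = 2).

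A limma F test found 2752 of 5656 genes (48.7%) changed over the cycle, 2527 of them at least 2-fold between their extremes. The point at 21 °C rising held the highest value of 793 of these genes and the lowest of 958. The point at 12 °C held the highest of 787 and the lowest of 714. With the point at 21 °C rising left out 1769 genes passed, but no other point was left out for comparison. A 24-h harmonic was called for 2466 genes, of which 349 peaked in hours 0 to 6, 927 in hours 6 to 12, 315 in hours 12 to 18 and 875 in hours 18 to 24. No array lay between hours 0 and 6 or between hours 12 and 18, so peaks placed there rest on the fitted sine wave. The term in phase with temperature was called for 1144 genes, the term 6 h out of phase for 1373 and both for 351. For genes changed over the cycle, temperature alone covered a median of 39.4% of the variance between time points and both terms 78.0%. These shares were taken on the same 6 means to which the terms were fitted. Any term covers some variance there, and a second term can only raise the share. The term in phase with temperature was called as higher in the warmth for 33 of 37 respiratory chain genes (37 adjusted over the list alone; camera adjusted p = 1.75e-20, but adjusted p = 0.168 with an estimated correlation). The mean of that list stood at -0.46 at 21 °C falling and 0.63 at 21 °C rising. The term 6 h out of phase was called as higher on the falling side for 71 of 95 ribosome biogenesis genes (83 adjusted over the list alone; camera adjusted p = 5.08e-23, but adjusted p = 0.48 with an estimated correlation). The cold shock genes TIP1 and TIR1, the desaturase gene OLE1 and the actin gene ACT1 did not pass the test over the cycle (adjusted p = 0.433, 0.547, 0.689 and 0.275). The cycle means of TIP1 (log2 12.68 to 13.14) and TIR1 (12.60 to 13.07) lay near the highest signals of the arrays. A change could be compressed there, so a response of these 2 genes is not excluded.

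**Figure D3:**
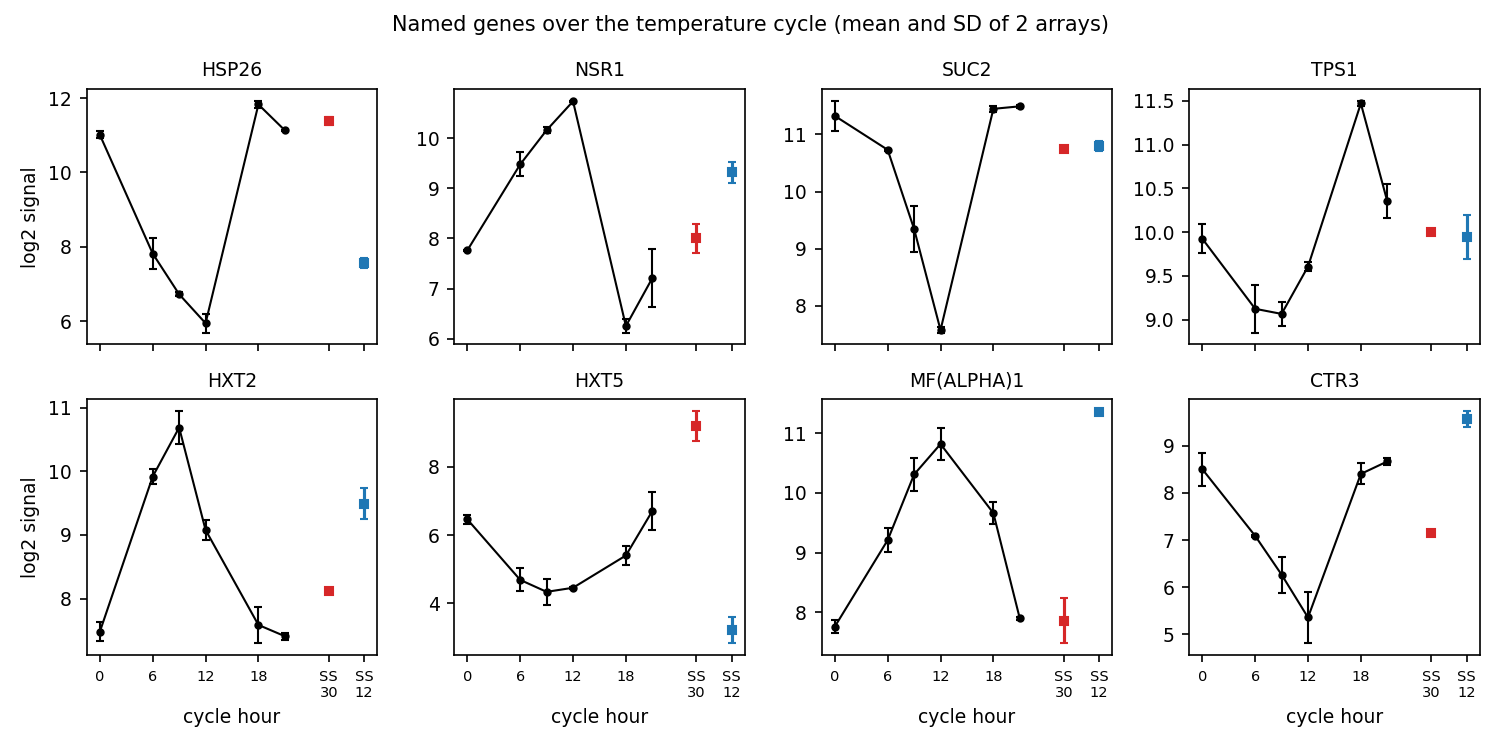
Log2 signal of 8 genes against the hour of the cycle (black, mean and SD of 2 arrays) and at steady state (red 30 °C, blue 12 °C). HSP26 was lowest at 12 °C in the cycle (5.94) and NSR1 highest there (10.73), TPS1 was highest at hour 18 (11.47), HXT2 at hour 9 (10.69), and CTR3 and SUC2 fell at the cold point only in the cycle.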

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

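The tests of explanations in this part were chosen after the results were seen, and the length correction was added then too, while the test of the difference was planned.

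The temperature effect differed between cycle and steady state for 729 genes in the test of the difference itself, and this difference is what singled out each gene below. The genes named as higher in the cycle had log2 differences of KTR2 5.75, SET2 4.87, SPS2 4.82, INO2 4.73, FUI1 4.69, YMR085W 4.51 and the transfer RNA genes YNCP0009W 4.43 and YNCE0004C 4.35. Those named as lower were CTR3 -5.56, the transfer RNA gene YNCK0017W -5.30, CTR1 -3.98, SUC2 -3.80, YRO2 -3.79, ZNF1 -3.70, YJL218W -3.68 and AIM33 -3.62. Sizes and order are not reliable where a group mean lay under background, which held for KTR2, SET2, SPS2, FUI1, YMR085W, ZNF1, AIM33 and the transfer RNA genes. With the floor of 12 the difference was 0.19 for SET2 (adjusted p = 0.377), 0.21 for SPS2 (adjusted p = 0.428) and -3.04 for ZNF1 (adjusted p = 0.0718), which then did not pass, while it was 1.64 for FUI1 and 4.59 for KTR2, which did. Among the index genes the difference was -2.14 for GPH1, -1.95 for GSY2, -1.54 for HSP12, -1.24 for HSP26, -1.59 for HXK1, 3.98 for HXT5, -0.89 for HXT7, 1.65 for NSR1 and -2.16 for TSL1. The HXT7 difference no longer passed in 14 of 23 alternatives (-0.40 after quantile normalization, adjusted p = 0.333), that of ZNF1 in 11 and that of HSP26 in 10. HXT5 also had a group mean under background, and its difference was 3.61 with the floor of 12. HXT7 shares nearly all its sequence with HXT6, so which gene its probe set reads is uncertain.

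Probe sets left out of the comparisons also carried signal. Of 2443 probe sets without a gene here, 955 lay above background and 235 of these changed over the cycle in a limma F test. Of 328 probe sets with several genes, 281 lay above background and 89 of these changed over the cycle.

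Ribosome biogenesis genes were higher at 21 °C falling than at 21 °C rising, by a median of 2.47 over 95 genes. Per-array scaling moves all genes alike, so it could not part the list from the genes outside it, which had a median difference of 0.023. That median is no test of scaling, since a common target for every array holds it near 0 in advance. The shift of the list is therefore known only relative to other genes. Gene length is argued against, since after the length correction the list's median was 2.47, 99.9% of its value. So is a single deviating array, since the smallest of the 4 array-to-array differences of the list mean was 2.48 and the largest 2.51. Whether the direction of temperature change, the hour of the cycle or another condition that went with them sets this difference was not tested, as the design ties them together.

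Replicate arrays differed from each other along gene length, with a rank correlation of their difference with length that ran from -0.396 to 0.626 over the 8 replicate pairs. The pair difference in this trend followed the pair difference in 18S ribosomal RNA control signal (Pearson's r = 0.912, exact permutation p = 0.00181, adjusted p = 0.00362 over 2 relations; Spearman's rho = 0.881, exact permutation p = 0.00724; r = 0.805 without the 2 farthest pairs). Unequal ribosomal RNA signal may therefore go with the trend, as a hypothesis from 8 pairs. Fragmented RNA would make the trend fall as the ratio of 3' to 5' ACT1 control signal rises, a negative r. The observed sign was the opposite, r = 0.469 (exact permutation p = 0.229, adjusted p = 0.229; Spearman's rho = 0.5, exact permutation p = 0.216; r = 0.676 without the 2 farthest pairs), and 8 pairs are too few to exclude that explanation by a value so far from the threshold. No biological explanation was tested, since replicates share a condition.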

How the results depend on the processing

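Alternatives that were added after the data were seen are the length correction, leaving out the 3 arrays that stood apart from their replicate (DTC_30 replicate 1, DTC_12 replicate 2 and DTC_27.4 replicate 2), the crossed numbering and leaving out the point at 21 °C rising. Both arrays of a pair lie equally far from their mean, so the pair alone does not tell which of them deviated. None of the gene changes followed through the alternatives turned round. Of their values 4184 stayed on the same side of the threshold, while 288 kept direction but no longer passed. The changes followed take in most of those named in the text as passing. Not followed were YKL107W in the cycle and the differences of YMR085W, YJL218W, YNCP0009W, YNCE0004C and YNCK0017W. The cause of the shifts below was not tested, except that a stricter threshold allows fewer calls by construction. The spread of replicates was unequal, with a median SD over genes of 0.145 at 21 °C rising, 0.151 at 21 °C falling and 0.288 at DTC_30. The shared spread of the main model can thus be too small for DTC_30 and too large at 21 °C. A fit with only the groups compared also has fewer residual degrees of freedom. With only the groups compared in the fit, limma called 685 genes for SS_12 versus SS_30, 782 for DTC_12 versus DTC_30, 343 for the difference of the effects, 0 for DTC_30 versus SS_30 (448 at an unadjusted p under 0.05) and 0 for DTC_12 versus SS_12 (1568 at an unadjusted p under 0.05), while both sides of 21 °C rose to 2398 from 1915. At an adjusted p under 0.01 the counts were 561, 1105, 267, 14 and 353 in the same order, 1254 for both sides of 21 °C, 1803 for the cycle and 1446 for the harmonic. For DTC_30 versus SS_30 the count was 106 with an intensity trend and robust prior, 17 with array weights (3 higher and 14 lower), 111 with the length correction and 27 without the 3 arrays, which also gave 582 for DTC_12 versus SS_12. Without the point at 21 °C rising 1769 genes changed over the cycle, and no other point was left out for comparison. The correlation of both effects was 0.489 after quantile normalization, 0.48 with the floor of 12, 0.424 with all probe sets, 0.483 with the length correction and 0.452 without the 3 arrays. An estimated correlation left 37 of 161 list calls.

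Leaving out single replicates gave 565 to 954 genes for SS_12 versus SS_30, 1225 to 1663 for DTC_12 versus DTC_30, 410 to 753 for the difference, 15 to 49 for DTC_30 versus SS_30, 365 to 703 for DTC_12 versus SS_12, 1290 to 1362 for both sides of 21 °C, 2119 to 2895 for the cycle, 2066 to 2466 for the harmonic and 0.439 to 0.466 for the correlation. Where this leaves a group with 1 array, that array is assumed to vary like the other groups. For DTC_30 versus SS_30 the split was 7 higher and 10 lower without SS_30 replicate 2, and 6 and 43 without DTC_30 replicate 2.

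The replicate numbers share no stated meaning. Over 15 pairs of cycle points the deviations of same-numbered arrays correlated from -0.473 to 0.519, with 3 pairs over 0.1 and 4 under -0.1. No steady pairing by number was visible in these values. Replicate arrays also differed along gene length, which could hide a shared culture, so whether the numbers mark the cultures stays open. With the number as a fixed replicate block the counts were 1263, 1853, 725, 70, 1014 and 1938 for the pairwise comparisons, 2760 for the cycle and 2296 for the harmonic. With the number as a random block they were 1230, 1731, 655, 60, 1029, 1837, 2578 and 2212. This block is a culture effect only if the numbers mark the cultures. Crossing the numbers of DTC_30 gave 1894 for DTC_12 versus DTC_30. Signal over background limits the dimmest genes, since 5368 of 5656 lay above it on average.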

Other observations

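Of what follows, the gene sets and the tests on alpha cells were chosen after the values were seen. Some amino acid permease genes were lower in the constant cold, as counts without a test of the group. Of 23 measured, 8 fell and 1 rose between SS_30 and SS_12, among them BAP3 (-4.53 ± 0.33 SE, adjusted p = 4.91e-06), MUP1 (-4.35 ± 0.37, adjusted p = 1.63e-05), PTR2 (-3.92 ± 0.30, adjusted p = 6.2e-06) and AGP1 (-3.84 ± 0.27, adjusted p = 3.48e-06). In the cycle 7 fell and 1 rose at 12 °C, and the difference between cycle and steady state was higher for 5 and lower for 1. PTR2, a peptide transporter gene counted with them, had a difference of 3.24 ± 0.42 (adjusted p = 0.000973) and stood at 8.10 ± 0.03 (SD, n = 2) at DTC_12 against 6.04 ± 0.33 (SD, n = 2) at SS_12.

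Copper genes parted from each other. Between steady states 2 of 9 rose and 4 fell at 12 °C, and in the cycle none rose and 4 fell. The transporter gene CTR3 stood at 9.56 ± 0.17 (SD, n = 2) at SS_12 and at 5.36 ± 0.55 (SD, n = 2) at DTC_12. The metallothionein gene CRS5 fell in both, by 2.34 ± 0.19 (adjusted p = 9.46e-06) at steady state and by 1.82 ± 0.19 (adjusted p = 3.73e-05) in the cycle. CUP2, the activator of copper resistance genes, fell by 1.38 ± 0.20 at steady state (adjusted p = 0.000704).

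The pheromone gene MF(ALPHA)1 was higher in the cold. Its log2 signal went from 7.76 ± 0.11 (SD, n = 2) at DTC_30 over 9.21 ± 0.21, 10.31 ± 0.28 and 10.82 ± 0.27 at DTC_12 to 9.66 ± 0.19 at 21 °C rising and 7.89 ± 0.02 at 27.4 °C, with a fitted peak at hour 12.3 (adjusted p = 1.67e-05). Alpha cells in the cultures would bring their other transcripts along. From DTC_30 to DTC_12 MF(ALPHA)1 changed by 3.06 and the alpha-specific genes STE3 and SAG1 by a mean of -0.662 (SE 0.2391), or -0.305 (SE 0.1766) with MF(ALPHA)2. Between SS_30 and SS_12 the mean of these 3 genes was 0.623 (SE 0.1766), with MF(ALPHA)2 at 1.56, STE3 at 0.51 and SAG1 at -0.20. MF(ALPHA)2 lay under background at SS_30, and its change was 1.16 with the floor of 12. STE3 and SAG1 lay above background in the warmth, where their signal would hide a small share of alpha cells. MF(ALPHA)1 itself fell from 10.82 at hour 12 to 7.89 at hour 21. A dilution rate of 0.03 per h replaced only a minor part of the culture in that time. This argues against a changing share of alpha cells behind the cycle pattern. Whether MF(ALPHA)1 changed within alpha or MATa cells stays open, as do alpha cells at SS_12. Of 7 genes specific to MATa cells, 2 rose and none fell from SS_30 to SS_12, and none passed from DTC_30 to DTC_12.

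The third array at 27.4 °C correlated with the first at 0.9759 and with the second at 0.9712, while those correlated with each other at 0.9617.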
